A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

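RNA levels were compared between a wild-type and a YDR374C deletion strain of the budding yeast Saccharomyces cerevisiae, both in the haploid laboratory background BY4741. Per the labels' protocols, cells grew in SD, a synthetic defined medium with glucose, to mid-exponential phase (OD600 0.7), total RNA was extracted with Trizol, and 0.2 ug was labelled with a two-colour Agilent kit. Wild-type RNA carried Cy3 (green) and the RNA labelled as deletion carried Cy5 (red) on both of the 2 arrays, so the dyes were not swapped and a dye effect that belongs to a gene stays in its ratio. The 2 arrays lay on 1 slide with 1 scan and carry the replicate numbers 1 and 2. The labels do not say whether they hold separate cultures, so p-values measure only the spread between these 2 arrays, which may be technical. Each array holds both strains, so strain and slide are not confounded, and no second slide exists as a batch.

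The deposited scanner files give each spot's intensity in both channels, with local background and quality flags, as Agilent Feature Extraction 9.5.3.1 wrote them per the file headers; the submitters' processing notes name version 9.3.2.1. The same deposited files hold a log10 ratio of red over green per spot after LOWESS dye normalization, per the file headers. The scanner software's p-value for that ratio is also in the deposited files. A deposited series table holds the authors' log2 values, 1 per probe and array. Set against the scanner ratios converted to log2, these ran in the same direction, red over green, with slopes of 0.985 and 0.988 and correlations across probes of 0.994 and 0.990. Their medians were -0.00491 and -0.000163, and how they were averaged and normalised is not given in the sources used here. No genome build is named in the files, so no coordinates are printed. Gene names came from the NCBI RefSeq table of assembly R64, which held 5756 of the 6256 systematic names; the other 500 kept the name in the file. Gene order along chromosomes came from the same table.

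Each array has 10789 spots, of which 526 are controls. The 6256 genes have 1 probe each, 4007 of them in 2 spots and 2249 in 1 spot. Mean signals were background-corrected with normexp (offset 50) against the median local background and normalised within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots that the scanner software marked as non-uniform or population outliers in either channel were left out (6.47% and 8.92% of gene spots on arrays 1 and 2); saturated spots were kept. Spots of a probe were averaged. A gene was tested if its remaining spots were well above background in at least 1 channel on both arrays, which left 5641 genes. Of the genes left out, 110 were not above background even with outlier spots counted. The rest were lost through outlier spots, and 6146 genes were tested when those spots were kept. The log2 ratio, deletion over wild type, was tested against 0 with limma's moderated test over the 2 arrays (prior df 13.2, prior SD 0.0505), with Benjamini-Hochberg adjustment and a threshold of 0.05; an absolute log2 ratio of at least 1 was a second limit. Values below are means over the 2 arrays with the standard error of that fit (SE, n = 2). Where a gene was not well above background in 1 channel on both arrays, a bound was computed per channel after loess and Aquantile normalisation; it is open to dye bias.

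36 gene lists were fixed before the data were examined, and the 35 with at least 3 tested genes were tested with camera (preset correlation 0.01), adjusted over these lists. Camera with an estimated correlation, fry and 10000 random lists matched on intensity in 20 bins were alternatives. Chromosome medians were compared with those of all other chromosomes by a two-sided permutation test with 100000 shuffles of the chromosome assignments, adjusted over 16 chromosomes. The genes named in the text were chosen by a rule set before the data were examined. It takes YDR374C and PHO4 always, the 12 largest higher and 12 largest lower log2 ratios past the test with 1 sign on both arrays, every measured member of the PHO regulon and of the genes beside YDR374C, and up to 4 members of each other list with the largest absolute log2 ratio and 1 sign on both arrays. Genes named outside it are said to be so.

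The tests were tried on simulated data. For the gene test, 2 arrays of 5641 genes with 200 changed genes were drawn; 95.5% of genes changed by 0.25 and 100% of those changed by 0.5 or by 1 on the log2 scale were called, with 0.0368% of unchanged genes. When each gene also carried a fixed dye bias with an SD of 0.1, 42.4% of unchanged genes were called. For the list test, 3.5% of 1000 random lists of 19 of the 5641 genes had p under the threshold, and so did 100% of 100 lists shifted by 0.5. Genes drawn at random need not vary together, so this does not check the error rate for lists of co-regulated genes. For the chromosome test on 5636 genes, 1 chromosome in all was called over 50 shuffled genomes, and a shift of 0.1 added to 1 chromosome was recovered as 0.0920. The alternatives were no background subtraction, normexp without an offset, median centring, the scanner software's own log ratios and p-values, the series table, both other filters on dim probes, scaling between arrays, an intensity trend and a robust fit, and each array left out. After the data had been seen, 3 more were added: outlier spots kept, saturated spots left out, and limma's treat test against a 1.5-fold change. With 2 arrays, precision is limited by their number. Chromosomes were also handled in Python 3.11.15 with numpy 2.4.6 and numba 0.67.0.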

Results

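RNA from a wild-type and a YDR374C deletion strain of budding yeast was compared on 2 two-colour arrays. YDR374C encodes Pho92, a protein with a YTH domain, a fold that binds methylated RNA, and its standard name ties it to phosphate metabolism. The comparison asks which RNAs change when this gene is removed, with the PHO genes, which the transcription factor Pho4 turns on when phosphate is scarce, as a group of interest. The median gene spot read 1597 (green, wild type) and 2105 (red) on array 1, and 2371 and 3105 on array 2. Local background medians lay between 36 and 42. Negative control spots read 140 and 126 on array 1 and 183 and 174 on array 2, green first. Between 96.9% and 98.1% of gene spots were well above background in a channel. Across 5641 tested genes, which are not independent replicates, the log2 ratios of the arrays correlated with r = 0.958 and rho = 0.948, and 89.6% of genes had 1 sign on both. Both arrays carry the dyes the same way round, so a fixed dye effect of a gene also adds to this agreement. The SD of the ratios over genes was 0.29 on array 1 and 0.28 on array 2, and the SD of the difference between arrays was 0.08.

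The deleted gene itself served as a check of the labels. PHO92 (YDR374C) had a log2 ratio of -0.23 ± 0.03 (SE, n = 2; limma adjusted p = 2.74e-05), but its signal did not disappear in the RNA labelled as deletion. Its probe lies in 2 spots, and the mean and its p rest partly on a spot at background. The first was not well above background in either channel on either array, with log2 ratios of -0.24 on array 1 and -0.39 on array 2. The second was well above background in both channels on both arrays, with processed signals of 271 (green) and 223 (red) on array 1 and 247 and 238 on array 2, and its log2 ratios were -0.24 and -0.04. BY4741 lacks LEU2, URA3 and MET17, and probes of these genes read between 9.13 and 182 in the green channel. In the red channel they read between 10.8 and 235. The highest red value on array 2, 235 for URA3, lay close to the 238 of the second PHO92 spot. On array 1 the highest was 174, also for URA3, against 223 for that PHO92 spot. The URA3 probe was well above background in both channels on both arrays. The position of the probe within YDR374C is not used here, so the check leaves open whether the RNA in the red channel lacked the transcript. The red channel is therefore called the RNA labelled as deletion, and every direction below rests on the dye labels. With the scanner software's own log ratios the value for PHO92 was -0.31 with adjusted p = 0.0879.

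Among the largest rises in the RNA labelled as deletion were those of GLC7, PHO5 and PHO11. GLC7, the catalytic subunit of protein phosphatase 1, was higher by 1.94 ± 0.04 on the log2 scale (SE, n = 2), a 3.84-fold difference with limma adjusted p = 2.25e-13. PHO5, the main secreted acid phosphatase, was higher by 1.91 ± 0.04 (3.75-fold), and its relatives PHO11 and PHO12 by 1.56 and 1.22. SPL2, which acts on low-affinity phosphate transport, and VTC3, a subunit of the complex that makes vacuolar polyphosphate, followed with 1.16 and 1.06. HGH1 (1.06), the ribosome assembly factor LOC1 (0.97), the glycerol phosphatase GPP2 (0.97) and the membrane heat shock protein HSP30 (0.95) were also among the 12 largest rises.

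The largest falls were smaller. YML122C, a small open reading frame, had a log2 ratio of -1.31 ± 0.03 (SE, n = 2) with limma adjusted p = 1.13e-12. COS12, of a family of genes near chromosome ends, had -1.10, and YGR176W, which is not in the gene table, also had -1.10. HUG1, an inhibitor of ribonucleotide reductase, had -1.07, YDR541C had -1.01 and RSC6, of the RSC chromatin remodelling complex, was next. VMA21, an assembly factor of the vacuolar proton pump, had -0.97, the DNA repair endonuclease APN1 had -0.94 and the mitochondrial import receptor TOM71 had -0.92. YIR016W had -0.92, and 2 ribosomal protein genes, RPL33A and RPL25, had -0.93 and -0.87. RPL33A has a near-identical copy, and probes of such copies may not tell them apart.

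Of 5641 genes, 2051 were higher and 2073 lower in the RNA labelled as deletion at limma's adjusted p threshold of 0.05, together 73.1%, and 1517 did not pass. The lower ones include 50 genes with a spot saturated in a channel on an array, 9 of them in both channels on both arrays, and the higher ones 27; the limit of the scanner enters these ratios, and 2023 lower genes had no saturated spot. Most of these differences were small: 53.4% of the called genes had an absolute log2 ratio under 0.25. An absolute log2 ratio of at least 0.5 was passed by 233 higher and 219 lower genes, and one of at least 1 by 8 higher and 6 lower genes. Tested against a 1.5-fold change, an alternative chosen after seeing the data, 40 genes were higher and 42 lower. With the scanner software's p-values under 0.01 on both arrays, 144 genes were higher and 142 lower. Some values given below moved by over 1.5 times with the call kept: those of PHM6, PPN1, CTF19, VPS74, LSM1, NOT5, DBP8, UGP1, STE6, MF(ALPHA)2, FUS1, TDH1, PDC1 and GLN1 after median centring, and those of PHM7, CTF19, SSP1, STE3 and MET28 with the scanner software's log ratios and the series table. URA3 moved so with the former only, and PHM7 also without array 1, where there is no test. Because the dyes were not swapped, the test against 0 counts a fixed dye effect of a gene as a difference, and the median SE of 0.0350 covers only the spread between the arrays.

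**Figure D1:**
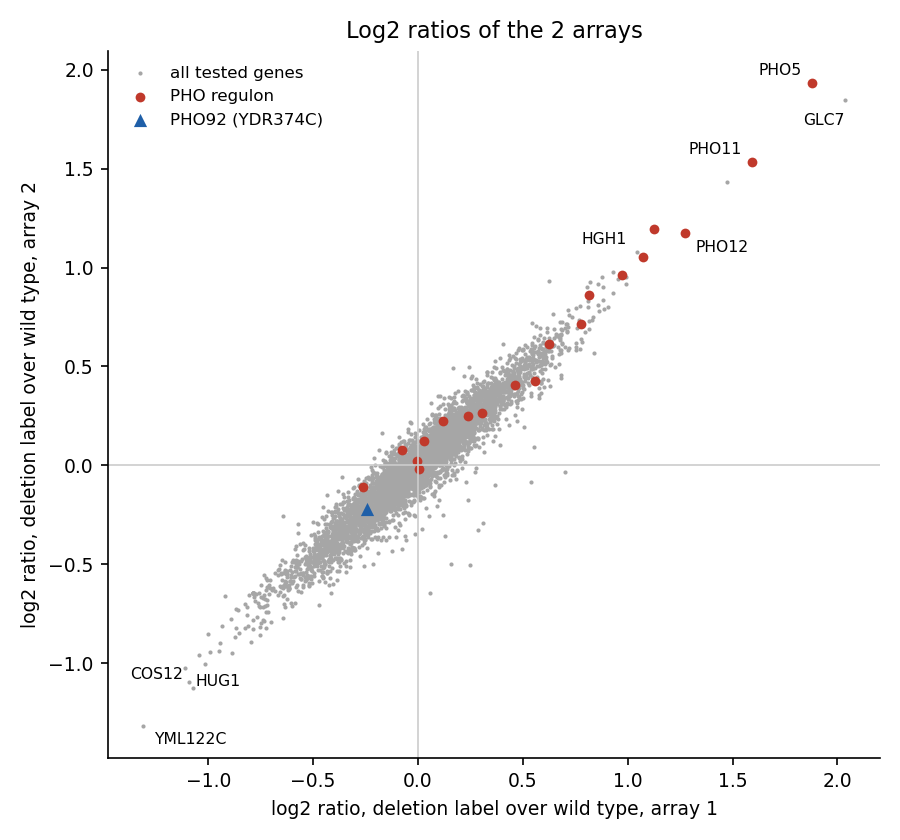
Log2 ratio of the RNA labelled as deletion over wild type on array 1 (horizontal axis) and array 2 (vertical axis), with 1 point for each of the 5641 tested genes, PHO regulon genes in red and PHO92 (YDR374C) as a blue triangle. The points lie along a line (r = 0.958), and GLC7 (1.94), PHO5 (1.91) and PHO11 (1.56) stand at the upper end.

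Genes of the PHO regulon rose together. Of 21 listed genes 19 were tested, 14 were higher and 1 was lower, and 4 did not pass; adjusted over the list alone the counts were also 14 and 1. The median log2 ratio was 0.49 (camera adjusted p = 3.45e-05), above all of 10000 random lists matched on intensity, whose highest median was 0.28. With an estimated correlation the list's call was lost (adjusted p = 0.909), as were those of all other lists. The estimate for this list was -0.053, below the preset 0.01, so a higher correlation did not cause the loss. That version of the test rests on the single degree of freedom that 2 arrays leave, so it cannot decide whether a list shifted. Fry, which tests a list against no change and not against the other genes, gave adjusted p = 0.0378. Besides the acid phosphatases PHO5, PHO11 and PHO12, the higher genes included subunits of the polyphosphate synthesis complex, VTC3, VTC1 (0.74 ± 0.04) and VTC4 (0.62 ± 0.03), and PHO86 (0.84 ± 0.04), which is needed for the export of a phosphate transporter from the endoplasmic reticulum. The sodium-phosphate transporter PHO89 was higher by 0.44 ± 0.04, the nucleotidase PHM8 by 0.49 ± 0.04, the polyphosphatase PPN1 by 0.29 ± 0.03, PHM6 by 0.24 ± 0.03 and CTF19 by 0.17 ± 0.04. PHO89 and CTF19 were dim, with mean log2 intensities over both channels of 8.45 and 8.29. URA3, a gene that BY4741 lacks, read 8.52 and was still called higher by 0.33, so these 2 calls are less secure. PHM7 was lower (-0.19 ± 0.04), but its red signal was not well above background on 1 array, which leaves the size open. VTC2 (0.08 ± 0.04), PHO81 (0.01 ± 0.03), PHO8 (0.00 ± 0.04) and GIT1 (-0.00 ± 0.03) did not pass. VTC2 passed after median centring, with 0.29. PHO84 and GDE1 were left out because the scanner software marked their spots as outliers on 1 array. PHO5, PHO11 and PHO12 are related in sequence, PHO11 and PHO12 most closely, and whether their probes tell them apart was not examined.

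**Figure D2:**
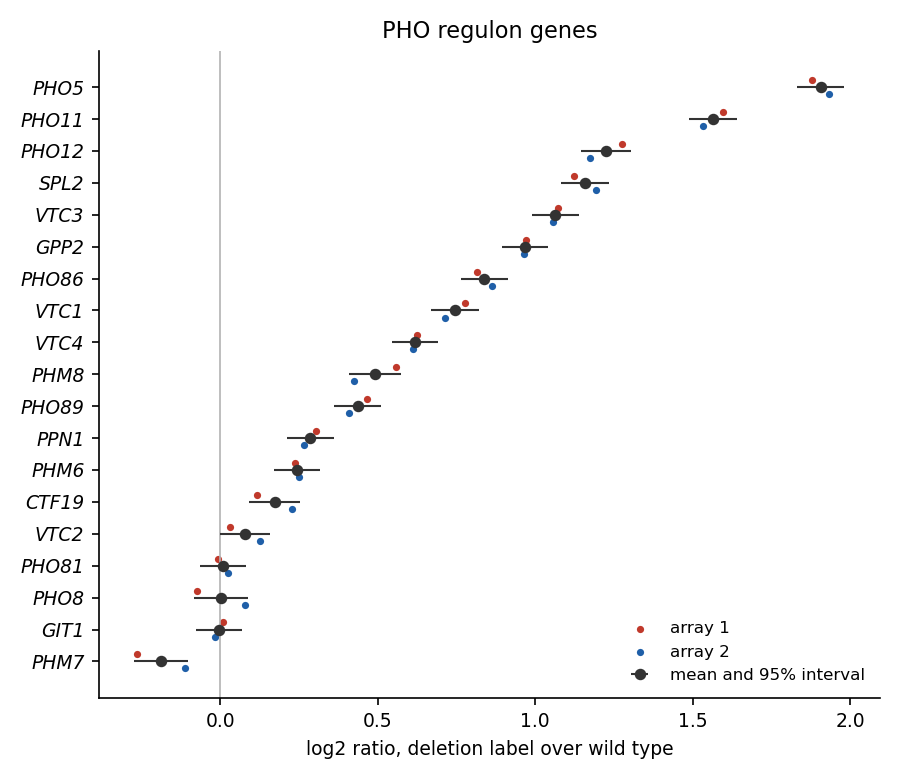
Log2 ratio of the RNA labelled as deletion over wild type (horizontal axis) for the 19 tested PHO regulon genes, with the mean and its 95% interval in black, array 1 in red and array 2 in blue. Values run from -0.19 for PHM7 to 1.91 for PHO5, and 14 genes lie above 0 past the test.

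PHO4, the transcription factor of this regulon, was itself higher by 0.60 ± 0.04 (SE, n = 2; limma adjusted p = 1.87e-09). The list of phosphate signalling and low-affinity transport genes, to which PHO4 belongs, did not shift as a group (median -0.03, mean 0.02, camera adjusted p = 0.971), with 4 of 12 genes higher and 4 lower. SYG1 was higher by 0.66 ± 0.04, while the cyclin PCL7 (-0.42 ± 0.03) and the low-affinity phosphate transporter PHO87 (-0.41 ± 0.04) were lower. Of the genes beside YDR374C on chromosome IV, 5 were tested. BCS1 (-0.46 ± 0.03) and ARH1 (-0.11 ± 0.03) were lower, VPS74 (0.20 ± 0.03) and CTS2 (0.09 ± 0.04) were higher, and FRQ1 (-0.01 ± 0.03) did not pass. CTS2 lost its call after median centring (0.04, adjusted p = 0.359). As a list they did not shift (median -0.01, camera adjusted p = 0.971).

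Genes of the G1/S transition of the cell cycle fell as a group. Of 29 genes 18 were lower and 7 higher, also adjusted over the list alone, with a median log2 ratio of -0.29 (camera adjusted p = 0.0217; adjusted p = 0.909 with an estimated correlation). The S-phase cyclin CLB6 (-0.87 ± 0.03), the transcriptional regulator TOS4 (-0.81 ± 0.03) and the G1 cyclins CLN1 (-0.77 ± 0.04) and PCL1 (-0.66 ± 0.04) fell most. GIC2, a higher member named after its value was seen, had 0.33 ± 0.04. With the series table's values the call missed the threshold (adjusted p = 0.0504). Genes of the following phases were 15 lower and 8 higher of 29, but the list did not pass (median -0.08, camera adjusted p = 0.177); CDC6 (-0.63 ± 0.04), SIC1 (-0.55 ± 0.03) and CLB1 (-0.55 ± 0.03) were its largest changes. Of 9 histone genes 6 were higher, among them HTA2 (0.38 ± 0.04), HHF2 (0.34 ± 0.04) and HTB1 (0.32 ± 0.03), and none was lower; the list did not pass (median 0.30, camera adjusted p = 0.153). It passed after median centring (median 0.41, adjusted p = 0.0266), and its median lay at percentile 99.1 of random matched lists.

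Oxidative phosphorylation genes and the iron regulon passed the list test by a narrow margin. Of 30 oxidative phosphorylation genes 17 were higher and 4 lower (median 0.12, camera adjusted p = 0.0485; adjusted p = 0.909 with an estimated correlation), also adjusted over the list alone. QCR9 of respiratory complex III (0.67 ± 0.03), the NADH dehydrogenase NDI1 (0.63 ± 0.03), COX4 of cytochrome oxidase (0.55 ± 0.04) and ATP4 of the ATP synthase (0.54 ± 0.04) led the list. Of 25 iron regulon genes 15 were higher and 3 lower (median 0.17, camera adjusted p = 0.0485; adjusted p = 0.909 with an estimated correlation), with the same counts adjusted over the list alone. Its leading members serve the uptake of iron bound to siderophores, namely ARN2 (0.68 ± 0.04), FIT2 (0.48 ± 0.04), ENB1 (0.47 ± 0.04) and the reductase FRE3 (0.38 ± 0.03). Fry passed neither list (adjusted p = 0.107 and 0.105), and the oxidative phosphorylation median lay at the 97.4th percentile of random matched lists. Both calls were also lost without an offset (both adjusted p = 0.0501) and with the series table (adjusted p = 0.0512 and 0.0504), and that of the iron regulon with outlier spots kept (median 0.10, adjusted p = 0.0503).

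A further 5 lists lay close to the threshold without passing it, with medians in both directions. Of 17 purine and one-carbon genes 13 were lower and 3 higher (median -0.20, camera adjusted p = 0.0509), with ADE2 (-0.62 ± 0.03), ADE8 (-0.54 ± 0.03) and ADE12 (-0.48 ± 0.04) lower and ADE16 (0.40 ± 0.04) higher. Of 48 amino acid biosynthesis genes 26 were lower and 9 higher (median -0.09, camera adjusted p = 0.0509), led by SER1 (-0.76 ± 0.04), ILV3 (-0.62 ± 0.03), HIS4 (-0.61 ± 0.04) and THR1 (-0.58 ± 0.04). Of 25 genes under nitrogen catabolite repression 14 were lower and 3 higher (median -0.18, camera adjusted p = 0.0509); glutamine synthetase GLN1 (-0.59 ± 0.04) and the permease genes PUT4 (-0.41 ± 0.04) and DAL4 (-0.39 ± 0.03) were among the lower ones. Of 40 listed ribosome biogenesis genes 30 were tested, with 19 higher and 7 lower (median 0.17, camera adjusted p = 0.0763). CBF5 (0.78 ± 0.05), IMP3 (0.53 ± 0.04) and NOP56 (0.50 ± 0.04) were higher and DBP8 (-0.57 ± 0.03) lower. The untested genes of this list were left out for outlier spots, and the list passed with those spots kept. Of 32 stress-induced genes 15 were higher and 6 lower (median 0.07, camera adjusted p = 0.0763), with PNC1 (0.90 ± 0.04), PIC2 (0.70 ± 0.04) and DCS2 (0.62 ± 0.03) higher and UGP1 (-0.66 ± 0.04) lower. In these 5 lists the counts adjusted over the list alone were the same. Each of them passed under at least 1 other setting.

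The ribosome itself did not shift in 1 direction. Of 137 listed cytosolic ribosomal protein genes 110 were tested. The others were left out for outlier spots, so the counts cover only part of the list. Of the 110 tested genes 50 were lower and 35 higher (median -0.04, camera adjusted p = 0.494), and 39 of the lower ones had no saturated spot. Without saturated spots the median was -0.01. After median centring the direction of this list turned, with a median of 0.14 and adjusted p = 0.0196. RPL37A (-0.84 ± 0.04) was lower and RPL17A (0.75 ± 0.04) higher. Of 51 mitochondrial ribosomal protein genes 21 were lower and 17 higher (median -0.01, camera adjusted p = 0.971).

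Genes of mRNA turnover and of meiosis, which are tied to YTH-domain proteins by their known biology, did not shift as groups. Of 22 genes of the CCR4-NOT complex and mRNA decay 12 were higher and 5 lower (median 0.12, camera adjusted p = 0.392), with LSM1 (0.43 ± 0.03), PUF3 (0.35 ± 0.03) and MPT5 (0.34 ± 0.03) higher and NOT5 (-0.39 ± 0.04, but -0.13 after median centring) lower. PUF3 was dim (mean log2 intensity 8.37), below URA3 (8.52), a gene that BY4741 lacks and that was called higher by 0.33. Of 23 genes of meiosis and RNA methylation 12 were lower and 7 higher (median -0.09, camera adjusted p = 0.494). MUM2 (-0.47 ± 0.03), a partner of the RNA methyltransferase, was lower, IME4, the methyltransferase gene, named after its value was seen, had 0.08 ± 0.03, ZIP1 had 0.36 ± 0.04, and the meiotic kinase MEK1 (-0.36 ± 0.04) and SSP1 (-0.31 ± 0.03) were lower. The red signals of SSP1 and of SPS4, given next, were not well above background on 1 array, which leaves the sizes open. The other sporulation markers were also named after their values were seen: SMK1 (0.25 ± 0.04) and DIT1 (0.24 ± 0.04) were higher, SPS4 (-0.28 ± 0.04) and DIT2 (-0.21 ± 0.04) lower, and SPS1 (0.05 ± 0.04) and SPR3 (-0.01 ± 0.04) did not pass.

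Markers of mating type did not separate the RNAs; STE2, MFA1 and MF(ALPHA)1 are named here after their values were seen. Among 6 MATa-specific genes AGA2 (0.34 ± 0.04) and STE2 (0.13 ± 0.04) were higher, STE6 (-0.62 ± 0.03), BAR1 (-0.43 ± 0.04) and MFA2 (-0.32 ± 0.04) were lower and MFA1 (-0.04 ± 0.03) did not pass (median -0.18, camera adjusted p = 0.518). Among 4 MATalpha-specific genes STE3 (-0.31 ± 0.03) and MF(ALPHA)2 (-0.08 ± 0.03) were lower, and SAG1 (-0.02 ± 0.03) and MF(ALPHA)1 (0.03 ± 0.04) did not pass (median -0.05, camera adjusted p = 0.616); adjusted over the list alone 1 of them was lower. The red signal of STE3 was not well above background on 1 array, which leaves its size open. MF(ALPHA)2 lost its call with the scanner software's log ratios (adjusted p = 0.0536) and with the series table (adjusted p = 0.0766). Of 20 genes of pheromone response and mating 10 were lower and 2 higher (median -0.11, camera adjusted p = 0.148), with FUS1 (-0.73 ± 0.03), PRM1 (-0.47 ± 0.04) and KAR4 (-0.47 ± 0.03) lower and the transcription factor STE12 (0.62 ± 0.04) higher. Of the marker genes that BY4741 carries in deleted form, URA3 was called higher by 0.33 ± 0.04 (limma adjusted p = 2.09e-06). HIS3, named after its value was seen, had -0.03 ± 0.04, and too few were tested for a list test. A call with a ratio of this size can thus appear for URA3, a gene that the BY4741 background lacks, and its cause was not tested.

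The remaining lists did not pass camera. Of 22 heat shock genes 9 were higher and 10 lower, 8 of these with no saturated spot, with HSP30 (0.95) and SSC1 (0.84 ± 0.04) at the top (median -0.04, camera adjusted p = 0.971). Of 22 cell wall genes 11 were lower and 7 higher, with CWP1 lowest at -0.84 ± 0.04 (median -0.09, camera adjusted p = 0.511); fry passed this list (adjusted p = 0.0124). Of the lower cell wall genes 9 had no saturated spot, and without saturated spots the medians of the cell wall and heat shock lists were both -0.00. Of 23 sulphur assimilation genes 9 were higher and 7 lower (median 0.04, camera adjusted p = 0.971). MUP1 (0.78 ± 0.04) was higher and MET10 (-0.71 ± 0.04) lower. MET28, not well above background in the red channel on either array, was at least 1.52-fold lower in the main setting (limma adjusted p = 1.28e-09). Over the settings its log2 ratio ran from -1.52 to -0.48, and the smallest size lies below that bound, so the bound depends on the processing. Of 26 genes of the TCA and glyoxylate cycles 12 were higher and 7 lower, led by LSC2 (0.60 ± 0.04), IDH1 (0.52 ± 0.04) and MDH1 (0.52 ± 0.04) (median 0.08, camera adjusted p = 0.392). Of 18 glycolysis genes 5 were lower and 4 higher, not counting ADH1 and CDC19, which were saturated in both channels on both arrays and have no fold (median with them -0.03, camera adjusted p = 0.511); TDH1 (0.43 ± 0.04) was higher and PDC1 (-0.43 ± 0.03) lower. Of the lower glycolysis genes 3 had no saturated spot, and without saturated spots the median was 0.01. Medians for hexose transport, ergosterol, phospholipid, thiamine, seripauperin, proteasome, unfolded protein and galactose genes lay between 0.00 and 0.06, with camera adjusted p between 0.858 and 0.971; that of hexose transport was 0.11 without saturated spots. Zinc regulon genes had a median of -0.07 (adjusted p = 0.494) and oxidative stress genes one of -0.12 (adjusted p = 0.392).

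No chromosome moved as a whole by a large amount. The median of the 492 tested genes of chromosome XV differed from that of all other chromosomes by -0.06 (adjusted p = 0.00016, permutation test) and that of the 393 genes of chromosome II by 0.05 (adjusted p = 0.00544, permutation test). The other 14 chromosomes did not pass, with adjusted p from 0.267 to 0.928. A second copy of a chromosome in a haploid strain would shift its genes by about 1 on this scale if RNA followed copy number.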

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

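The values in this part come from spots left out of the main comparison, and keeping them was an alternative chosen after seeing the data. For 3 genes, every spot on 1 array was marked as an outlier by the scanner software, and the spots as read gave an absolute log2 ratio of at least 1 with the same sign on both arrays. PHO84, the main high-affinity phosphate transporter and a member of the PHO regulon, had a log2 ratio of 1.34, deletion label over wild type, with 1.39 on array 1 and 1.30 on array 2. GDE1, the other PHO regulon gene left out for such spots, had a log2 ratio in the opposite direction, -0.25 (adjusted p = 1.88e-05). YGP1, a secreted glycoprotein in the list of stress-induced genes, had 1.03. AGE2, a regulator of Arf GTPases, had -1.09. These values are open to whatever made the software mark the spots.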

How the results depend on the processing

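The alternatives were planned before the data were examined, except keeping outlier spots, leaving out saturated spots and testing against a 1.5-fold change, which were chosen after seeing the data. Counts at the adjusted p threshold stayed within 1.5 times the main counts under all of them but 2. The scanner software's p-values gave 144 higher and 142 lower genes, and the 1.5-fold test 40 and 42. The former changes ratios, error model and threshold at once. Counts at an absolute log2 ratio of at least 1 (8 higher, 6 lower) moved to 1 lower without background subtraction, to 14 higher after median centring, to 18 higher and 12 lower with the scanner software's log ratios, to 17 and 11 with the series table, and to 17 and 10 with the scanner software's p-values; the cause was not tested. All 14 genes past both limits were shared with 6 of the 9 other ways of making the values, and between 9 and 12 with no background subtraction, median centring and outlier spots kept. In the main setting and these 9, between 49.2% and 50.1% of the called genes were higher.

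For PHO92 (YDR374C) the sign held throughout, but the call was lost with the scanner software's log ratios (-0.31, adjusted p = 0.0879) and with the series table (-0.16, adjusted p = 0.0813). The correlation of the arrays was 0.945 with the scanner software's log ratios, 0.943 with the series table, 0.956 without the filter on dim probes and 0.964 without saturated spots. The PHO regulon kept its direction and its call under each way of making the values and with fry. It lost the call with an estimated correlation (median 0.49, adjusted p = 0.909), a version in which no list passed and which 2 arrays leave undecided. G1/S genes lost it there (median -0.29) and with the series table (-0.31, adjusted p = 0.0504). Oxidative phosphorylation lost it without an offset (0.13, adjusted p = 0.0501), with the series table (0.13, adjusted p = 0.0512), with fry, with an estimated correlation and against random lists (each 0.12). The iron regulon lost it without an offset (0.18, adjusted p = 0.0501), with the series table (0.20, adjusted p = 0.0504), with outlier spots kept (0.10, adjusted p = 0.0503), with fry and with an estimated correlation (each 0.17). Cytosolic ribosomal proteins turned to 0.14 after median centring, and TSA1 to 0.0115; no cause was tested. Without saturated spots the ribosomal median was -0.01, that of cell wall genes -0.00 and that of glycolysis 0.01, none past the test. With 1 array left out, which leaves no test, the oxidative phosphorylation median ranged from 0.12 to 0.17 and the iron regulon median from 0.12 to 0.18. The PHO regulon aside, 17 list medians moved past their own SD between arrays without array 1 and 8 without array 2. That SD is smallest where arrays agree, so the counts do not measure stability. Some small medians differed by over 1.5 times, as in sulphur assimilation, glycolysis (-0.04 on array 1, -0.09 on array 2) and the zinc regulon. Chromosomes II and XV passed in the main setting, and 2 passed under each of the 9 other ways of making the values. Of 1870 comparisons of named genes with an alternative, 171 without array 1 and 171 without array 2 have no test. Among the others, 6 lost the call (CTS2, YDJ1, HXT3 and CWP2 after median centring, MF(ALPHA)2 with 2 other sources of ratios). A further 1 gained it (VTC2), and 1 that had passed, TSA1, changed sign. There were 10 more changes of sign, all in genes that did not pass: PHO8, PHO81, GIT1 and FRQ1. The median of probes was not run (1 probe per gene), nor were chromosome ends left out (no genome build is named).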

Other observations

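The comparison of the PHO regulon with random lists was planned, while its use against dye bias and the tests of the acid phosphatases and of growth stage were chosen after the result had been seen. Among genes outside the fixed lists, named after their values were seen, LYP1 (0.89), a lysine permease, RAS2 (0.89), a GTPase upstream of protein kinase A, and PPN2 (0.82), a vacuolar polyphosphatase, were higher in the RNA labelled as deletion. XBP1 (0.74), a repressor of cyclin genes, was also higher. CIN5 (-0.85), a stress transcription factor, TEC1 (-0.84), a regulator of filamentous growth, and FAR1 (-0.71), which arrests the cycle in response to pheromone, were lower. All of these passed limma's adjusted threshold.

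The rise of the PHO regulon was set against 3 explanations. Gene-specific dye bias of single probes would leave the list's median within the range of random lists, but 0.49 lay above the highest of 10000 (0.28), which argues against unrelated biases as the whole cause. Cross-hybridisation among the related acid phosphatase genes would not raise the other members, but the 16 others had a median of 0.36, above the highest of their random lists (0.31). A later growth stage would lower ribosome biogenesis genes and raise stress-induced genes; the former lay at percentile 99.6 of random lists, the opposite direction, and the latter at percentile 94.2, so this cannot be told apart from the deletion by these lists. The deletion and a difference in phosphate between cultures remain open and untested, and a dye swap would be needed for single genes.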
